A study of Mus musculus with 8 samples.

How the data were processed

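RNA of mouse morulae was measured in 8 libraries, 4 of embryos cultured with 0.1% DMSO and 4 of embryos cultured with 2 µM A485. Per the labels' protocols, 3 embryos without zona pellucida were pooled per library, polyadenylated RNA was reverse transcribed, the cDNA was preamplified with a low-input kit and libraries were made with a transposase. The culture protocol runs from the 4-cell to the blastocyst stage, while the samples are labelled as morulae. The labels name no batch, and strandedness is not given in the sources used here.

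The submitters' processing notes name HISAT2 2.2.1, RSEM 1.2.28, DESeq2 1.40.2 and the build GRCm38.p6. The authors deposited 1 table of 18257 genes, all of type mRNA, so noncoding genes such as Xist, and mitochondrially encoded genes, were not analysed here. Per the file headers, it gives for each library an estimated count (18.2% of values are not whole), an FPKM value, a TPM value and a normalized count (the estimated count divided by 1 factor per library, which the deposited values show as a scaled signal). The authors' deposited table also holds their log2 fold change of A485 over control and its DESeq2 p-value and q-value. All tests here used the estimated counts, rounded to whole numbers; 13 genes had no count left. FPKM, TPM and normalized counts of the authors entered no test. Totals per library were 23641781 to 25677701. PCR copies cannot be told from separate molecules in these counts, so the counting interval given for Asprv1 covers counting error only.

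Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr on group, TMM factors, quasi-likelihood fit with robust dispersion, group as the only term), with Benjamini-Hochberg adjustment over 12936 genes and a threshold of 0.05. A standard error of a log2 fold change is the fold change divided by the square root of its F statistic. CPM means use TMM-scaled library sizes. Log2 CPM has a prior count of 2. Each pool is a biological replicate per the labels' protocols; nothing says whether pools came from separate litters or culture days.

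Before the data were examined, 40 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested genes (38) were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists. The mitochondrial list had no gene in the table and the sperm list 3 tested genes. Of 1250 list members 1209 were found by symbol. The rule names the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and whose average log2 CPM is at least 3 (predicted and Riken genes counted, not named), up to 4 genes of smallest p in each called list and in the lists on repair, checkpoint, p53, apoptosis, linker histones and lineage, and a fixed set including Ep300, Crebbp, Trp53 and every linker histone. Some genes that the rule names are not reported here. Library measures were compared with an exact two-sided permutation test over 70 assignments.

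Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter, a filter of 5 CPM in 4 libraries, non-robust dispersion, a replicate block, an estimated correlation, fry, and leaving out each library. Total-count scaling and leaving out A485 replicates 1 and 2 or 3 and 4 were added after seeing the data. No replicate pair agreed within sampling noise. The chi-square per degree of freedom was 20.4 to 36.4 for control pairs and 65.3 to 228.6 for A485 pairs. A485 libraries thus varied more, while both groups shared 1 dispersion trend in the fit. Coordinates come from an NCBI gene table of GRCm38.p6, in which 18205 of 18257 identifiers were found. Transcript lengths and GC content came from GENCODE transcripts.

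The code was tested on simulated data, with counts drawn from the control means and 200 genes changed, for A485 versus control over 11972 genes. edgeR recovered 3.0% of genes changed 1.5-fold, 36.9% of those changed 2-fold and 78.7% of those changed 4-fold, with 4.4% false calls. DESeq2 recovered 10.6%, 52.3% and 85.2% with 21.1% false calls. The simulation changed 200 genes and 1 list, against 7077 genes past the threshold in the data. It also gave both groups the same dispersion, while A485 libraries varied more in the data. These rates therefore need not hold in the data. A list moved as a whole in the simulation was called, and 0 unmoved lists were. Genes were drawn independently there, so this does not test list calls where genes vary together. In the data the estimated correlation reached 0.888, for ribosomal proteins. Gene Ontology terms came from the authors' annotation columns. Enrichment of terms was tested with Fisher's exact test, for an excess only, among tested genes in Python 3.11.15 with scipy 1.17.1.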

Results

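Polyadenylated RNA of mouse morulae was sequenced after culture with A485, an inhibitor of the acetyltransferase activity of the coactivators p300 and CBP. Control embryos were cultured with 0.1% DMSO and treated embryos with 2 µM A485, both from the 4-cell stage onward. Each group had 4 libraries, and each library pooled 3 embryos, which the labels call 1 biological replicate. The total estimated count per library lay between 23641781 and 25677701. After a filter on low counts, 12936 genes were tested.

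The comparison of A485 with control addresses what p300/CBP inhibition changed in the transcriptome of the morula, with DNA repair and apoptosis named in the title of the series. Cdx2, a transcription factor required for the trophectoderm, fell from 50.8 ± 10.9 to 1.94 ± 1.18 CPM (SD, n = 4 per group), and Nanog, a pluripotency factor, fell from 292 ± 111 to 32.0 ± 16.7 CPM (SD, n = 4 per group). Ldha, encoding lactate dehydrogenase A, rose from 52.0 ± 15.7 to 829 ± 128 CPM (SD, n = 4 per group). Hmox1, encoding haem oxygenase 1, rose from 49.7 ± 18.7 to 2945 ± 670.4 CPM (SD, n = 4 per group).

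In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7077 genes passed an adjusted p of 0.05, with 3839 higher and 3238 lower in A485. A change of at least 2-fold was seen in 4718 of them, 2874 higher and 1844 lower. Of 12450 autosomal genes tested 29.2% rose and 25.4% fell, and the counts of lists below are to be read against these shares. The libraries of each group lay entirely on 1 side of the other group's for 51.5% of tested genes, where chance gives 2.86%. Of the genes that passed, 54.2% were higher, and 68.2% were higher when libraries were scaled by total counts without a composition factor, which moved the median log2 fold change of all genes from 0.085 to 0.372. Without a spike-in, a change in RNA per embryo cannot be seen, so each rise or fall is relative to the other genes. In the authors' deposited table, 7999 genes had a q-value under 0.05. Of these 7212 were tested here, where 6997 passed in the same direction and 0 in the opposite direction.

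The 10 largest rises among well-covered genes whose groups did not overlap were those of Mt3, Asprv1, Calml4, Tdpoz1, Vax2, Gng3, Mzb1, Tmem59l, Tfpi and Isg20. Tfpi, encoding an inhibitor of the coagulation pathway, went from 0.786 ± 0.360 to 109 ± 8.96 CPM (SD, n = 4 per group), and Mt3, a metallothionein, from 0.0553 ± 0.0833 to 53.2 ± 28.6 CPM. These genes were close to absent from control embryos, with at most 22 counts of Tfpi in any control library. Asprv1 had 3 counts over the control group and 2391 over the A485 group, a ratio of 665.6 after division by TMM-scaled library sizes, with a 95% counting interval of 227.5 to 3230. Without control replicate 1 the log2 fold changes fitted by edgeR were 10.1 for Asprv1 (9.12 with all libraries), 13.01 for Calml4 (8.79), 11.4 for Mt3 (9.78) and 9.81 for Tdpoz1 (7.95), which had 7.29 without A485 replicate 2. Without control replicate 4 that of Gng3 was 8.34 (7.34). Tdpoz1 belongs to a family of near-identical copies, so its count is uncertain. The 10 largest falls were those of Tat, Sept12, Prl3b1, Tdh, Cd84, Msc, Bhmt2, Cdx2, Allc and Gdf3. Without A485 replicate 1 the log2 fold changes of Tat, Sept12, Tdh, Cd84, Bhmt2 and Allc were -8.29, -6.46, -6.10, -5.88, -5.64 and -5.38, against -7.70, -5.59, -5.13, -5.05, -5.02 and -4.64 with all libraries, and that of Msc was -5.87 without A485 replicate 4 (-5.04). Tat, encoding tyrosine aminotransferase, fell by 7.70 ± 0.66 on the log2 scale (SE), and Gdf3, a TGF-beta family ligand of pluripotent cells, fell from 78.9 ± 8.09 to 3.38 ± 0.769 CPM (SD, n = 4 per group).

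Among inner cell mass and pluripotency genes, 23 of the 34 tested fell, 3 rose and 8 did not pass. Pou5f1 fell from 845 ± 98.5 to 293 ± 79.3 CPM (SD, n = 4 per group), and Tfcp2l1 and Tdgf1 fell, with log2 fold changes of -3.29 ± 0.25 and -3.19 ± 0.30 (SE). Nodal, a signalling ligand, rose with a log2 fold change of 5.29 ± 0.44 (SE), from 0.154 to 6.24 CPM. Sox2 had a log2 fold change of -1.0 ± 0.84 (SE; edgeR adjusted p = 0.33) at under 1 CPM in both groups. The list was lower than other genes in camera (adjusted p = 0.00012 with the preset correlation), and the call was lost with a correlation estimated from the data (adjusted p = 0.57 with an estimated correlation). Adjusted over the list alone, 23 fell and 3 rose, and with the 5 CPM filter, which tests fewer genes, 18 fell and 1 rose. Cdx2 lies on chromosome 5 at 147300900 to 147307249, and Nanog on chromosome 6 at 122707489 to 122714633 (GRCm38.p6).

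Trophectoderm genes went both ways, with 18 of the 33 tested higher, 9 lower and 6 not past the threshold. Gata3, a transcription factor of the trophectoderm, fell from 84.6 ± 15.7 to 16.1 ± 6.44 CPM (SD, n = 4 per group), and Tspan8 fell by 2.66 ± 0.22 on the log2 scale (SE). Lgals3, encoding galectin 3, rose from 18.3 ± 1.43 to 769.5 ± 325 CPM, and Dsp, encoding the desmosomal protein desmoplakin, from 7.14 ± 1.52 to 46.9 ± 17.2 CPM (SD, n = 4 per group). Chosen after their values were seen, the transcription factor genes Tfap2c and Tead4 had log2 fold changes of -1.77 ± 0.27 and -1.23 ± 0.24 (SE), while the keratin genes Krt8 and Krt19 had 1.71 ± 0.26 and 6.31 ± 0.80 (SE). Camera gave an adjusted p of 0.20 for the list, and adjusted over the list alone 19 rose and 9 fell. In the primitive endoderm list 7 of 22 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.30), with 11 higher and 3 lower under total-count scaling, 12 and 6 without A485 replicates 1 and 2, and 4 and 2 with the 5 CPM filter. Its transcription factor Gata6 fell from 45.6 ± 7.43 to 15.1 ± 9.87 CPM, whereas Sparc, an extracellular matrix gene, rose from 15.8 ± 4.46 to 264 ± 103 CPM (SD, n = 4 per group). Apoe, Srgn and Serpinh1 rose with log2 fold changes of 2.98 to 4.14.

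**Figure D1:**
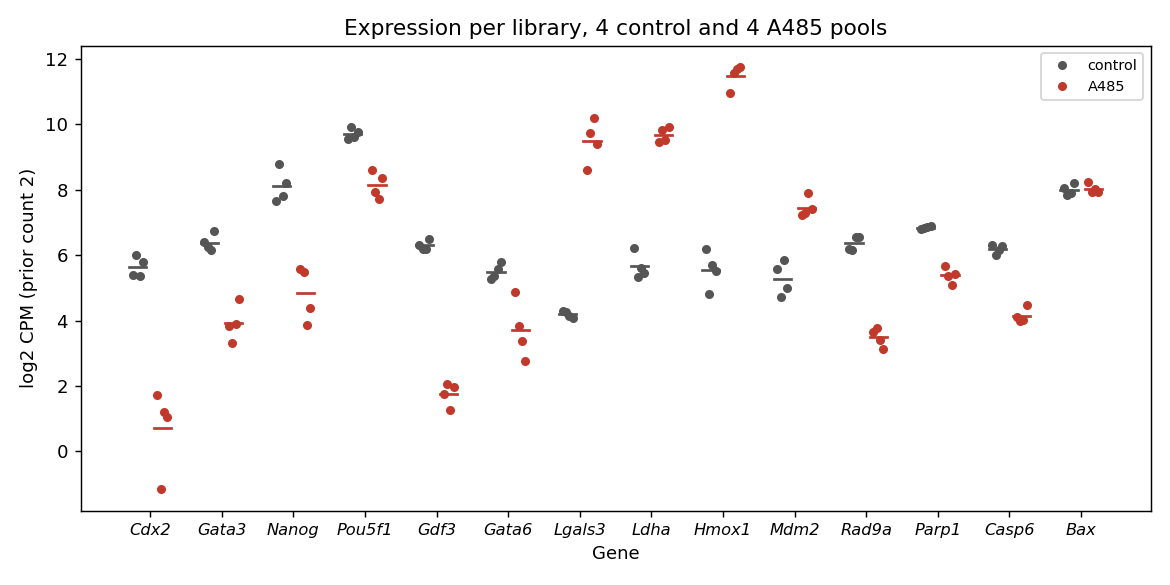
Log2 CPM of 14 named genes in each library. Points are the 4 control (grey) and 4 A485 (red) libraries, and bars are group means. The groups do not overlap for any gene plotted except Bax.

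In base excision and single-strand break repair 13 of 26 fell and 6 rose, the same counts adjusted over the list alone. Parp1, encoding the poly(ADP-ribose) polymerase that binds DNA breaks, fell from 115 ± 3.89 to 42.0 ± 6.88 CPM (SD, n = 4 per group). Aptx and Mutyh fell, with log2 fold changes of -1.49 ± 0.13 and -1.95 ± 0.25 (SE), and Neil3, a DNA glycosylase gene, rose with a log2 fold change of 3.80 ± 0.49 (SE), or 4.39 without control replicate 3. In homologous recombination 11 of 38 fell and 2 rose, against 9 and 2 adjusted over the list alone, and Rad54b, Exo1, Rad52 and Mus81 fell, with log2 fold changes from -0.83 to -1.73. Under total-count scaling 7 fell and 5 rose, with the 5 CPM filter 8 and 1, and without A485 replicates 3 and 4 10 and 1. Brca1 and Brca2, chosen after their values were seen, did not pass (log2 fold changes of -0.35 ± 0.26 and -0.095 ± 0.30, SE). In nucleotide excision repair 12 of 24 fell and 6 rose, against 13 and 6 adjusted over the list alone, with Gtf2h2, Gtf2h4 and Rad23b lower and Cetn2 higher, and under total-count scaling 8 fell and 8 rose. In mismatch repair 4 of 12 fell and 1 rose on both adjustments, with Rfc4 lower and Rfc5 higher. Under total-count scaling 2 fell and 2 rose, and without A485 replicates 1 and 2 8 fell and 2 rose. In the Fanconi anaemia pathway 5 of 16 fell and 0 rose, against 2 and 0 adjusted over the list alone. Faap20 and Fancl fell, with log2 fold changes of -1.17 ± 0.14 and -1.02 ± 0.18 (SE), and Fancm and Usp1 fell less. The list had 3 fallen members without control replicate 2, A485 replicate 2 or A485 replicate 3, and 2 without control replicate 4. In it 2 fell and 2 rose under total-count scaling, 2 and 1 with the 5 CPM filter, 2 and 0 with upper-quartile factors, 3 and 0 without A485 replicates 3 and 4, and 8 and 0 in DESeq2. The call of Fancm was lost without control replicate 1 or 4 or A485 replicate 2 (log2 fold changes from -0.58 to -0.46, edgeR adjusted p of 0.061 to 0.077), and that of Usp1 without control replicate 2, 3 or 4 or A485 replicate 2, 3 or 4 (log2 fold changes from -0.46 to -0.37, edgeR adjusted p of 0.051 to 0.094). Both calls were also lost with upper-quartile factors (adjusted p = 0.0578 and 0.0702), the 5 CPM filter (0.0572 and 0.0797) and total-count scaling (0.225 and 0.377), and that of Usp1 with a replicate block (0.0688). In non-homologous end joining 4 of 18 fell and 3 rose on both adjustments, with Xrcc5 and Xrcc6 lower and Setmar and Shld2 higher. Under total-count scaling 2 fell and 5 rose, and Xrcc6 lost its call (edgeR adjusted p = 0.054).

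Of the checkpoint signalling genes 7 of 29 fell and 2 rose, the same adjusted over the list alone, and 1 rose without control replicate 1. Under total-count scaling 5 fell and 5 rose, and without A485 replicates 1 and 2 12 fell and 2 rose. In checkpoint signalling, end joining and homologous recombination the share that fell was close to the 25.4% of autosomal genes. A smaller share of each list rose than the 29.2% of autosomal genes. Rad9a, encoding a subunit of the clamp that is loaded at DNA damage, fell from 83.2 ± 13.2 to 11.3 ± 2.13 CPM (SD, n = 4 per group). Chek1 and Hus1 fell, with log2 fold changes of -1.25 ± 0.24 and -1.4 ± 0.28 (SE), and Topbp1 rose with a log2 fold change of 1.36 ± 0.20 (SE). No DNA repair or checkpoint list passed the camera test, with adjusted p of 0.054 for homologous recombination, 0.057 for base excision repair, 0.16 for mismatch repair, the Fanconi pathway and checkpoint signalling, 0.19 for nucleotide excision repair and 0.86 for end joining. Homologous recombination passed without any single control replicate or without A485 replicate 1 or 4 (adjusted p of 0.022 to 0.048), and base excision repair without control replicate 1, 2 or 4 or A485 replicate 1 (adjusted p of 0.030 to 0.048). Homologous recombination also passed with RLE factors (0.0472) and a replicate block (0.0421). With an estimated correlation neither passed (adjusted p = 0.735 and 0.566). With fry, which called 11 lists higher and 11 lower, every repair and checkpoint list except end joining was lower. The fry adjusted p was 0.00969 for homologous recombination, 0.00205 for base excision and for mismatch repair, and 0.00109 for nucleotide excision repair. It was 0.000712 for the Fanconi pathway, 0.00513 for checkpoint signalling and 0.708 for end joining.

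Of the p53 target genes 17 of 37 rose and 2 fell, on both adjustments. Mdm2, encoding the ubiquitin ligase that acts on p53, rose from 40.8 ± 14.7 to 179 ± 42.1 CPM (SD, n = 4 per group), and Trp53inp1, Plk3 and Apaf1 rose with log2 fold changes of 1.56 to 3.28. Trp53 itself fell from 148 ± 8.43 to 92.9 ± 22.8 CPM (SD, n = 4 per group). Cdkn1a had a log2 fold change of 0.39 ± 0.32 (SE; edgeR adjusted p = 0.32) and Bax of 0.02 ± 0.13 (SE; edgeR adjusted p = 0.89). The list was higher than other genes in camera (adjusted p = 0.015), but not with an estimated correlation (adjusted p = 0.79 with an estimated correlation). Without control replicate 4, 10 of its members rose, and without A485 replicates 1 and 2 its camera call was lost (adjusted p = 0.071).

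Pro-apoptotic genes went both ways, with 13 of 38 higher and 9 lower, against 13 and 10 adjusted over the list alone (camera adjusted p = 0.86). These shares were close to those of autosomal genes, of which 29.2% rose and 25.4% fell. Casp6, an executioner caspase gene, fell from 73.3 ± 7.26 to 17.8 ± 2.90 CPM (SD, n = 4 per group), Htra2 and Dffb fell with log2 fold changes of -1.99 ± 0.19 and -1.43 ± 0.15 (SE), and the death receptor gene Tnfrsf1a rose with a log2 fold change of 2.81 ± 0.31 (SE). Bik and Casp8, chosen after their values were seen, rose with log2 fold changes of 5.89 and 4.19. Of the anti-apoptotic genes 5 of 18 fell and 2 rose on both adjustments (camera adjusted p = 0.43), but 1 fell and 4 rose under total-count scaling, and 5 fell and 1 rose in limma-voom. Ptma, Api5 and Bag3 fell, with log2 fold changes of -1.22, -0.49 and -0.63, and Tmbim6 rose with a log2 fold change of 0.71. Api5 and Bag3 lost their call under total-count scaling. Bcl2 was not past the filter on low counts.

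Of the 6 linker histone genes tested, 2 fell and 1 rose, against 2 and 0 adjusted over the list alone (camera adjusted p = 0.43). H1f0 fell from 48.7 ± 12.7 to 17.6 ± 8.98 CPM (SD, n = 4 per group). H1f4 fell by 2.26 ± 0.76 on the log2 scale (SE) and H1f8, the oocyte linker histone, rose with a log2 fold change of 1.17 ± 0.45 (SE), both at under 2 CPM. The call of H1f4 was lost without control replicate 1, 2 or 4 or A485 replicate 3 (log2 fold changes from -2.32 to -1.99, edgeR adjusted p of 0.057 to 0.071), and that of H1f8 without control replicate 1, 3 or 4 or A485 replicate 1, 2 or 4 (log2 fold changes from 0.87 to 1.24, edgeR adjusted p of 0.080 to 0.10). The list then had 1 fallen or 0 risen members, and without A485 replicate 2 H1f4 had a log2 fold change of -3.06. The call of H1f8 was also lost with RLE factors (adjusted p = 0.0528), without a filter (0.0777) and with a replicate block (0.076), and that of H1f4 under total-count scaling (0.0517), where 1 member fell and 1 rose. With the 5 CPM filter 1 fell and 0 rose. H1f5 had a log2 fold change of -1.92 ± 0.88 (SE; edgeR adjusted p = 0.088), which passed without A485 replicate 1 (-3.44, edgeR adjusted p = 0.004), in limma-voom (adjusted p = 0.0126) and with a replicate block (0.0441), H1f1 of -0.16 ± 0.59 and H1f2 of 0.13 ± 0.47 (SE). Replication-dependent histone messages mostly lack a poly(A) tail, so selection for polyadenylated RNA measures them poorly. Ep300 and Crebbp, the genes of p300 and CBP, rose with log2 fold changes of 1.17 ± 0.36 and 0.75 ± 0.20 (SE), and the call of Ep300 was lost without control replicate 3, control replicate 4 or A485 replicate 2 (edgeR adjusted p of 0.060 to 0.061).

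Genes of ribosome biogenesis fell in 41 of 52 cases and none rose, against 43 and 0 adjusted over the list alone and 35 and 1 under total-count scaling. Lyar fell from 202 ± 11.8 to 60.3 ± 14.9 CPM (SD, n = 4 per group), and Rrp9, Imp4 and Pes1 fell, with log2 fold changes from -1.27 to -1.87. Of the ribosomal protein genes 39 of 77 fell and 1 rose on both adjustments, with Rpl3 going from 4013 ± 394 to 2203 ± 418 CPM (SD, n = 4 per group) and Rpl14 and Rpl5 at log2 fold changes from -0.80 to -0.92. Many ribosomal protein genes have near-identical pseudogenes, so their counts are uncertain. The number that fell was 19, 23, 24 and 25 without control replicate 2, control replicate 4, A485 replicate 2 and A485 replicate 3, 68 without A485 replicate 1 and also without A485 replicates 1 and 2, 16 without A485 replicates 3 and 4, and 18 under total-count scaling, where 4 rose. None rose without a filter, without any single control replicate or without A485 replicate 4. Both lists were lower in camera (adjusted p = 1.0e-09 and 8.1e-06) and neither was with an estimated correlation (adjusted p = 0.74 and 0.80 with an estimated correlation). With fry ribosome biogenesis passed (adjusted p = 0.00389) and ribosomal proteins did not (adjusted p = 0.0649).

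DNA replication genes fell in 22 of 45 cases and rose in 7, against 23 and 8 adjusted over the list alone, and Tyms, encoding thymidylate synthase, fell from 688 ± 33.8 to 185 ± 26.7 CPM (SD, n = 4 per group). Orc5, Rfc4 and Pold2 fell, with log2 fold changes of -1.17, -1.17 and -1.77. Without control replicate 4, 4 rose. Under total-count scaling 14 fell and 11 rose, and the camera call (adjusted p = 0.020) was lost there (adjusted p = 0.063), with the 5 CPM filter (adjusted p = 0.166) and with an estimated correlation (adjusted p = 0.74 with an estimated correlation). Cholesterol and lipid synthesis genes fell in 14 of 30 cases and rose in 3 on both adjustments, and 1 rose without A485 replicates 3 and 4. Scd1 and Elovl6, encoding a fatty acid desaturase and an elongase, fell, with log2 fold changes of -2.05 ± 0.23 and -2.18 ± 0.30 (SE), Stard4 fell by 1.47 ± 0.19 and Sc5d rose with a log2 fold change of 1.39 ± 0.19 (SE). The camera adjusted p was 0.015, or 0.0846 with the 5 CPM filter and 0.74 with an estimated correlation.

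In glycolysis 17 of 22 genes rose and 0 fell, against 18 and 0 adjusted over the list alone. Eno1, Gpi1 and Pgk1 rose with log2 fold changes of 2.82 ± 0.21, 2.16 ± 0.14 and 3.24 ± 0.25 (SE). Among oxidative stress defence genes 20 of 30 rose and 6 fell on both adjustments, and Prdx1, a peroxiredoxin gene, rose from 709 ± 60.6 to 3132 ± 749 CPM (SD, n = 4 per group). Prdx2 and Gclm rose with log2 fold changes of 2.46 ± 0.15 and 2.76 ± 0.26 (SE). Of the imprinted genes 16 of 24 rose and 2 fell on both adjustments, and 9 rose with the 5 CPM filter, which tests fewer of them. Phlda2 and Cdkn1c, maternally expressed genes that restrain growth, rose with log2 fold changes of 5.03 ± 0.31 and 4.22 ± 0.35 (SE), Gnas rose with 2.39 ± 0.18 and Snrpn fell by 1.54 ± 0.14 on the log2 scale (SE). Camera placed the 3 lists above other genes (adjusted p = 1.6e-06, 0.0045 and 0.0011). With an estimated correlation none was called (adjusted p = 0.57, 0.71 and 0.28 with an estimated correlation).

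**Figure D2:**
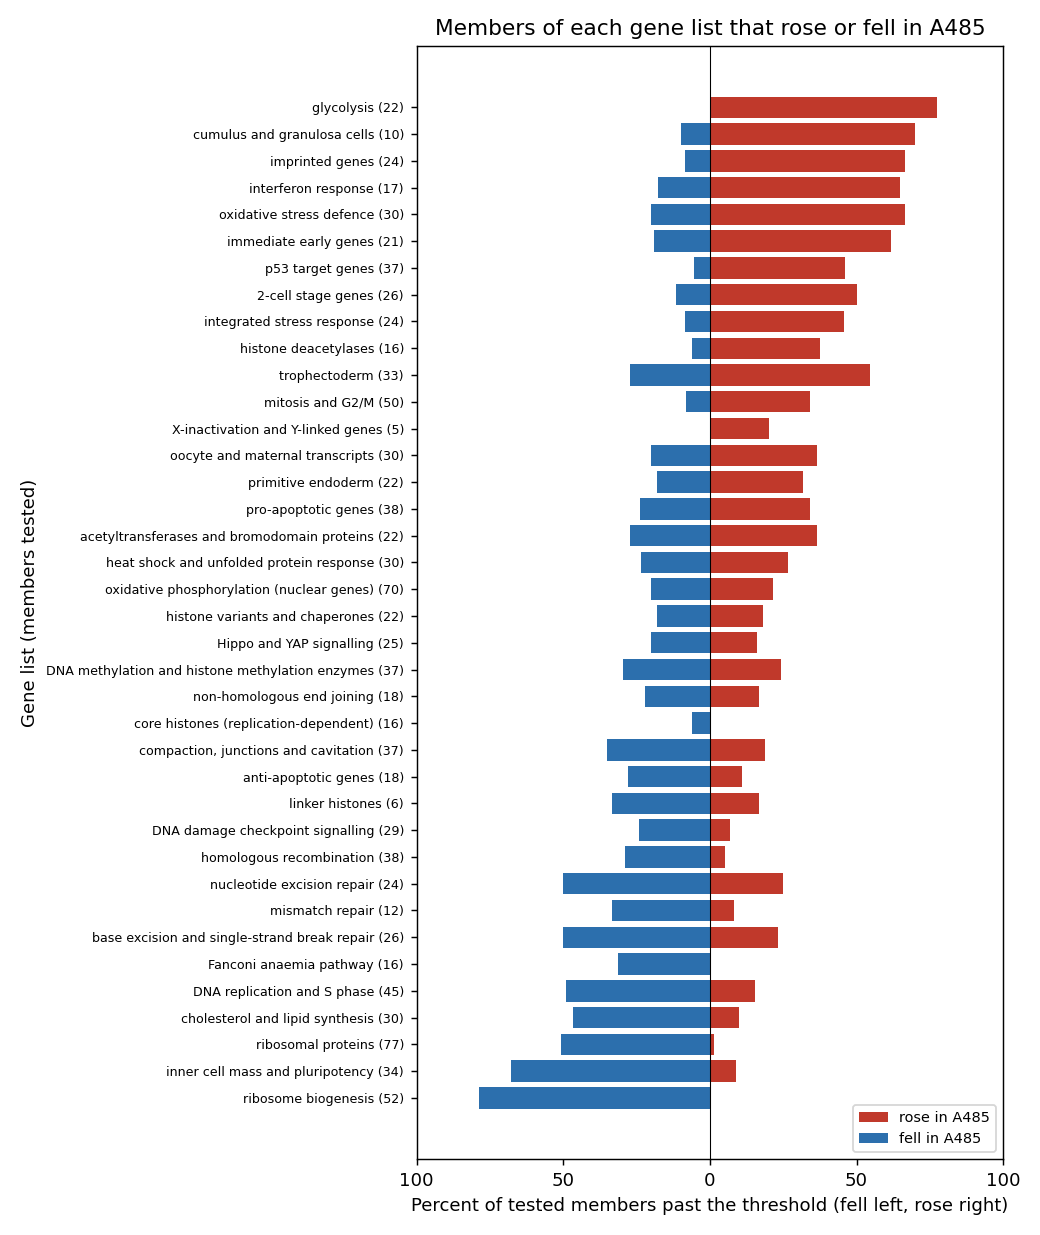
Percent of tested members of each gene list that rose (red, right) or fell (blue, left) in A485 at an edgeR adjusted p under 0.05, with the number tested in parentheses. Glycolysis had 17 of 22 members higher, and ribosome biogenesis had 41 of 52 lower. Of 12450 autosomal genes tested 29.2% rose and 25.4% fell.

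The other lists did not pass camera. Of genes of the 2-cell stage 13 of 26 rose and 3 fell, of interferon response genes 11 of 17 rose and 3 fell, and of integrated stress response genes 11 of 24 rose and 2 fell. The 2-cell list passed without A485 replicates 3 and 4 (adjusted p = 0.00118), but with all libraries its adjusted p was 0.187, or 0.908 with an estimated correlation. Immediate early genes rose in 13 of 21 cases and fell in 4 (14 and 4 adjusted over the list alone). Mitosis genes rose in 17 of 50 cases and fell in 4, with 11 higher and 9 lower without A485 replicate 4 and 11 higher without control replicate 4, and oocyte and maternal transcripts rose in 11 of 30 and fell in 6. Histone deacetylases rose in 6 of 16 cases and fell in 1 (5 and 1 adjusted over the list alone; 3 fell without A485 replicate 1 and 2 without A485 replicate 4), and acetyltransferases and bromodomain proteins rose in 8 of 22 and fell in 6. Genes of compaction, junctions and cavitation fell in 13 of 37 cases and rose in 7 (14 without A485 replicate 1), and Hippo and YAP signalling genes fell in 5 of 25 and rose in 4 (5 and 3 adjusted over the list alone). Enzymes of DNA and histone methylation fell in 11 of 37 cases and rose in 9, and heat shock and unfolded protein response genes rose in 8 of 30 and fell in 7. Nuclear genes of oxidative phosphorylation rose in 15 of 70 cases and fell in 14 (14 and 12 adjusted over the list alone). Histone variants and chaperones rose in 4 of 22 cases and fell in 4, with 2 higher without control replicate 3 and 7 lower without A485 replicate 1. Of 16 replication-dependent core histones 1 fell and 0 rose, with 2 lower without A485 replicate 1 or 2, 1 higher without control replicate 1 or A485 replicate 2 and 2 higher without A485 replicate 4. Without A485 replicates 1 and 2 that list passed (adjusted p = 0.0219), but with all libraries its adjusted p was 0.404, or 0.908 with an estimated correlation. Of the 5 X-inactivation and Y-linked genes tested 1 rose (0 adjusted over the list alone, and 0 without control replicate 1 or 3 or A485 replicate 2 or 4), and of 3 sperm genes tested 1 rose. Where no second count is given, the counts were the same adjusted over the list alone. Under total-count scaling 27 mitosis genes rose and 2 fell, 30 genes of oxidative phosphorylation rose and 8 fell, 15 of compaction rose and 11 fell, 10 histone variants and chaperones rose and 3 fell, 9 acetyltransferases and bromodomain proteins rose and 3 fell, and 1 core histone rose and 1 fell. With the 5 CPM filter, which tests fewer genes, 5 genes of the 2-cell stage, 4 of the interferon response, 5 oocyte and maternal transcripts, 5 acetyltransferases and bromodomain proteins and 2 Hippo and YAP genes rose, but 24 of oxidative phosphorylation did. Without A485 replicates 1 and 2, 10 genes of the 2-cell stage rose and 7 fell, 16 of compaction rose and 14 fell, 6 histone variants and chaperones rose and 7 fell, 6 histone deacetylases rose and 3 fell, 10 integrated stress response genes rose and 4 fell, and 4 core histones fell. Without A485 replicates 3 and 4, 9 mitosis genes and 4 core histones rose, and 0 X-inactivation and Y-linked genes did. In limma-voom 8 genes of the 2-cell stage rose.

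In the cumulus and granulosa list 7 of 10 tested genes rose and 1 fell (8 and 1 adjusted over the list alone, 13 and 1 without a filter, 1 and 1 with the 5 CPM filter; camera adjusted p = 0.057). The mean log2 CPM of these 10 genes, of 29 in the list, was 0.35 ± 0.16 in control and 2.202 ± 0.33 in A485 (SD, n = 4 per group). Means of lists cover tested genes only, and the filter keeps genes expressed in A485 alone, so this mean can favour a rise. The cumulus and granulosa list passed without any single control replicate or without A485 replicate 1 or 4 (camera adjusted p of 0.0057 to 0.036), but not with an estimated correlation (adjusted p = 0.566). At least 1 count was seen for 15203 ± 158 genes in control and 15792 ± 257 in A485 libraries, and the 50 most counted genes held 22.1 ± 0.513% and 19.1 ± 0.938% of counts (SD, n = 4 per group). For each of these 3 measures, and for the mean of the trophectoderm list, the two-sided exact permutation p was 0.029, the smallest that 70 assignments can give, and none passed after adjustment over 8 measures (adjusted p = 0.057). Total count, the share of ribosomal protein genes, the share of predicted genes and the mean of the oocyte list had exact permutation p of 0.37, 0.14, 0.83 and 0.11. On the second axis of multidimensional scaling A485 replicates 1 and 2 lay at -1.54 and -1.12, and A485 replicates 3 and 4 at 1.04 and 1.41. Without the first pair 4292 genes were higher and 3782 lower, and without the second pair 3470 and 3164.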

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

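The tests of Y-linked genes and of low-abundance genes, including cumulus cells, were chosen only after the results they bear on had been seen.

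Among 242 groups of 4 libraries examined, 10 held a library whose gap to its nearest neighbour exceeded Dixon's 95% limit for 4 values, where chance gives about 12.1. In log2 CPM, these were Aptx in A485 replicate 4 (5.75), Calml4 in control replicate 1 (-1.21), Chek1 in A485 replicate 1 (4.40), H1f5 in control replicate 4 (1.12), Htra2 in A485 replicate 4 (3.69), Mzb1 in control replicate 4 (-3.63), Rpl3 in control replicate 2 (12.2), Scd1 in A485 replicate 4 (5.13), Srgn in A485 replicate 3 (5.37) and Tfpi in control replicate 3 (-1.60).

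The first pattern weighed is the number of genes past the threshold. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 7077 genes, and the highest of the others gave 0. The same held for the 3839 higher, the 3238 lower and the 4718 genes with at least 2-fold change, each reached by 1 of the 35 splits with 0 in the highest of the others. The other splits mix control and A485 libraries, so the difference between control and A485 widens the spread within their groups. Their counts of 0 are thus no measure of chance alone, and 1 of 35 is the smallest share possible. This comparison therefore does not exclude chance. GC content and transcript length explained 0.7% of the variance of log2 fold changes over 12522 genes, which argues against them as the cause. The labels name no batch, so none was tested. The counts of lists did not stand out when each other split was counted by its larger direction, higher or lower. On that count 30 of the 35 splits gave as many as the 4 higher lists (highest other 8). As many as the 5 lower lists were given by 22 (highest other 8). The mixing of control and A485 libraries holds for lists as well, so these splits do not measure chance alone. Chance is not excluded for the lists.

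The second pattern is the rise of X-linked genes. Of 451 tested on the X chromosome 44.8% rose and 14.4% fell, against 29.2% and 25.4% of 12450 autosomal genes (Fisher's exact p = 6.3e-12 across genes, which are not independent). Low abundance does not account for it, since 0% of 10000 autosomal sets matched on abundance had a median as high as 0.54 (highest 0.36). The loss of a 2-fold dosage reduction stays open. It would cap the rises near 1 on the log2 scale, which 54.5% of the risen X-linked genes exceeded by more than 2 SE, but so did 45.5% of the risen autosomal genes, so the share does not decide. A larger share of female embryos in the A485 pools stays open, because 5 Y-linked genes, with a mean log2 fold change of 0.01, went apart: LOC115489304 had -1.80 ± 0.31 and Uba1y 1.66 ± 0.80 (SE), while Uty, Eif2s3y and Ddx3y lay from -0.026 to 0.12. Their mean log2 CPM differed by -0.09 ± 0.30 between groups (SE over libraries), too wide to exclude a fall of 0.5.

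The third pattern is the rise of low-abundance genes: with an average log2 CPM of 0 to 2, 37.1% of 2935 genes rose, against 19.2% of genes at 6 to 8, of which 44.6% fell. Below 0, 26.7% of 1174 genes rose and 10.8% fell, so rises were most frequent at 0 to 2 and not at the lowest abundance. Better recovery of every low-abundance transcript in A485 libraries, acting alone, would leave few falls, but 12.8% of the 2935 genes fell. True falls could remain beside a gain in recovery, so this does not exclude a partial gain. Falls did grow rarer toward low abundance, with 32.5% of genes at 4 to 6 and 20.7% at 2 to 4. Cumulus or granulosa cells in the A485 pools stay open, although the zona pellucida, with any cells attached to it, was taken off and the embryos were washed before lysis. Of their marker genes under 1 CPM in control, 20.8% (5 of 24; 95% binomial interval 7.1% to 42.2%) reached 1 CPM in A485: Cyp11a1 (15.1 CPM), Nr5a1 (2.04), Inha (1.45), Hsd3b1 (1.36) and Star (1.22). Col1a2, Dcn and Has2 stayed under 0.05 CPM, but most of these values lie near the floor. Of the markers that control embryos also express, Serpine2 went from 51.4 to 218 CPM, Vim from 1.82 to 7.55, Npr2 from 1.45 to 3.01, Amhr2 from 28.3 to 33.4 and Nr4a1 from 9.89 to 2.53. Derepression of silent genes under A485 was not tested.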

How the results depend on the processing

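Total-count scaling, the runs without 2 A485 libraries and both HIF alternatives were chosen after seeing the data. The count of genes past the threshold stayed within 1.5 times under every alternative run. With a filter of at least 5 CPM in 4 libraries, which tests 8194 genes, 2526 genes were higher and 2576 changed at least 2-fold. Without single libraries, 6478 to 7685 genes passed, 3509 to 4165 higher, 2785 to 3520 lower and 4459 to 5304 by at least 2-fold. For lists, 0 were higher and 0 lower with an estimated correlation, 11 and 11 with fry, 3 lower with the stricter filter, and 8 lower without A485 replicates 1 and 2, where the call of p53 targets was lost (adjusted p = 0.071). Without single libraries 4 to 5 lists were higher and 5 to 7 lower. The cause was not tested. Equal replicate numbers did not pair the samples throughout (correlations of deviations of 0.005, 0.014, 0.104 and 0.067). Control replicates 1 and 2 were closest to A485 replicates 2 and 1 (0.117 and 0.143), but control replicates 3 and 4 to A485 replicates 3 and 4. Across groups, correlations within replicates 1 and 2 or within 3 and 4 were all positive (0.005 to 0.143). Those between these sets were all negative (-0.127 to -0.019). A split shared by both groups is thus not excluded, and its cause was not tested. With the replicate block 6671 genes passed, 3508 higher and 3163 lower. The alternative without mitochondrial genes was not run, since the table holds none, and pseudocounts do not apply to counts.

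Results that never passed the threshold changed sign as follows, and the cause was not tested. Bax had a log2 fold change of -0.0318 without a filter, -0.0534 without A485 replicates 1 and 2 and -0.0586 to 0.0741 without single libraries. H1f1 had 0.0819 under total-count scaling, 0.49 without A485 replicates 3 and 4 and -0.86 to 0.14 without single libraries, and H1f2 had -0.52 without A485 replicates 1 and 2 and -0.31 to 0.46 without single libraries. The share of predicted genes differed by -0.273 to 0.141 percentage points without single libraries. Adjusted p of lists that turned direction were, with fry, 0.913 for histone variants, 0.218 for acetyltransferases, 0.988 for oxidative phosphorylation and 0.708 for end joining. With the stricter filter they were 0.881 for histone variants and 0.527 for oxidative phosphorylation. Under total-count scaling they were 0.742 for histone variants and for acetyltransferases, 0.872 for oocyte transcripts and 0.455 for oxidative phosphorylation. Without A485 replicates 1 and 2 it was 0.858 for compaction, and without 3 and 4 it was 0.988 for acetyltransferases and 0.849 for heat shock. Without single libraries they ranged from 0.611 to 0.97 for histone variants, 0.77 to 0.998 for acetyltransferases, 0.354 to 1 for oxidative phosphorylation and 0.772 to 0.991 for heat shock.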

Other observations

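The tests of Gene Ontology terms, HIF target genes and the oocyte list were chosen after the changes in these embryos had been seen.

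Of 1460 Gene Ontology process terms, 36 held more risen genes and 32 more fallen genes than the 12936 tested genes would give. Fisher's exact test was run for an excess only, with Benjamini-Hochberg over 2920 tests. Genes are not independent, so these p are too small. Among rises were glutathione metabolic process (38 of 57 genes, adjusted p = 4.0e-06), cell migration (93 of 199, adjusted p = 6.4e-05), response to hydrogen peroxide (31 of 49, adjusted p = 0.00022) and regulation of cell shape (62 of 127, adjusted p = 0.0007). Of 34 terms on apoptosis 2 held more risen genes, positive regulation of apoptotic process (119 of 305, adjusted p = 0.019) and of neuron apoptotic process (36 of 64, adjusted p = 0.0013), and 0 more fallen genes. A term of the opposite sense outside these 34, negative regulation of neuron death, also held more risen genes (30 of 54, adjusted p = 0.0059). Risen terms thus covered both promotion and restraint of cell death. Of 17 terms on DNA repair or damage 0 passed in either direction, and the smallest adjusted p was that of DNA repair (113 of 361 fell, adjusted p = 0.095). Among falls were translation (165 of 286, adjusted p = 4.9e-29), tRNA processing (55 of 98, adjusted p = 3.4e-08), RNA splicing (100 of 263, adjusted p = 0.00032) and tRNA aminoacylation (20 of 34, adjusted p = 0.0031). Genes annotated to the cellular response to leukemia inhibitory factor, a cytokine that sustains pluripotent cells, fell in 50 of 113 cases (adjusted p = 0.001). Chromosome 18 stood second to the X in its median log2 fold change (0.38), with 112 of 294 genes higher and 47 lower.

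Rising glycolysis genes may reflect activation of HIF target genes. A list of 42 HIF targets outside glycolysis, written after some of its members had been seen to rise, was tested against other genes: 17 of 39 tested rose and 4 fell, and camera gave p = 0.0592 upward (p = 0.17 with an estimated correlation). A redraft of the list, made before either version was tested, left out 8 members, some of which had been seen to rise, and gave a limma camera p of 0.24, with 31 members tested and 11 higher. Neither version passed, and a p over the threshold does not exclude the hypothesis, so it stays open.

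Lower Cdx2, Gata3 and Nanog could mean that embryos were held at an earlier stage. Oocyte and maternal transcripts, which might then be higher, rose in 11 of 30 cases and fell in 6. The limma camera p of the list was 0.776, so it does not decide between the explanations. Culture with A485 began at the 4-cell stage, so a hold after that stage need not raise oocyte transcripts. Of genes of the 2-cell stage 13 of 26 rose and 3 fell (camera adjusted p = 0.187). Of trophectoderm genes 18 of 33 rose and 9 fell (camera adjusted p = 0.198). The explanation stays open.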
